A study of Rattus norvegicus with 6 samples.

How the data were processed

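Circular RNA (circRNA) was profiled in lung tissue of 6-week-old male rats on 6 one-colour arrays, 3 from rats kept in 10% oxygen for 21 days and 3 from rats kept in normoxia for the same time. Per the labels' protocols, the lungs were perfused with buffered saline, total RNA was extracted with Trizol, linear RNA was digested with RNase R, and the remaining RNA was amplified with random primers and labelled with Cy3. RNase R degrades RNA with free ends and spares closed circles. The labels number the samples within a group without saying that each came from its own animal, so p-values measure the spread between these samples.

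Per the file headers, the spot and background intensity values came from Agilent Feature Extraction 11.0.1.1, which subtracted the background and detrended each array on its own, and did not normalize between arrays. The multiplicative part of the detrending was applied on all arrays but normoxia 1. The 0 or 1 flags for spots well above background, saturated or outlying were set by the same software, per the file headers. The authors also deposited log2 values, in 1 column per array. Its column medians were 6.09, 6.08, 6.09, 6.10, 6.08 and 6.08 for normoxia 1 to 3 and hypoxia 1 to 3, and the 6 columns shared one maximum, 17.56. Each column tracked that array's spot medians across circRNAs, with Spearman's rho from 0.998 to 1.000, and no centring of probes was seen; which background treatment and offset preceded the log2 step stays unknown. The submitters' processing notes also name limma, with no role. The genome build in the file headers was rn4.

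The main values were log2 of the processed signal minus the 75th percentile of the array over non-control probes. Of 14145 circRNA probes, each with 1 spot, the 12024 that were well above background on at least 3 of the 6 arrays were tested with lmFit and eBayes in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05 over the probes tested. A looser count took unadjusted p under 0.05 with a change of 1.5-fold or more. Array measures were compared by an exact permutation test, in which 3 against 3 allows no p below 0.10. Files were read with the R package data.table, version 1.17.8, and plots drawn with matplotlib 3.10.9. The number of arrays limits the precision.

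The arrays also carried 82 non-control probes in 10 or 20 spots each. Of these, 62 had the accession of a linear transcript and 39 matched a gene symbol through RefSeq names of assembly GRCr8, whose coordinates were not used because the builds differ. Spots of a probe were averaged without outlier flags, and 34 probes with at least a 0.5 share of spots above background on 3 arrays or more were tested with limma in the same way. This test was chosen after the files had been seen. Probes of one gene were kept apart.

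The circRNAs to be named were fixed before the data were examined: those past the adjusted threshold with groups that did not overlap, by fold change, then those with the smallest unadjusted p at 1.5-fold or more. The files do not pair circRNA identifiers with host genes, so at most 2 identifiers per direction are given. For the same reason the planned tests of 17 host gene lists and of circRNA classes could not be run. The lists were used only to group the linear transcript probes.

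The labels give both groups the numbers 1 to 3 without saying what a number marks. Deviations from the group means correlated across circRNAs by 0.55, 0.71 and 0.21 within the same-numbered pairs. In these deviations each array correlated best, among the arrays of the other group, with its own number. The values themselves did not show this for every array. Hypoxia 1 correlated by 0.9347 with normoxia 1 and by 0.9525 with normoxia 3, and hypoxia 3 by 0.9569 with normoxia 3 and by 0.9671 with normoxia 2. Because every pair exceeded 0.1, a rule fixed before the calls were compared, the numbers were taken to pair the samples, and counts with the replicate number as a block are given beside those without it where they differ. The pairing comes from the values, not from a stated design, and the same values were then fitted with it. The p-values of the blocked fit may therefore be too small. Pair 3 was weakly marked: hypoxia 3 correlated by 0.21 with normoxia 3 and by 0.18 with normoxia 1. The deviations of the 3 arrays of a group cancel out, so the correlations of the 3 pairs depend on each other. Passing 0.1 in every pair is therefore weaker evidence than 3 separate results would be. Whether the numbers matched by chance was not tested.

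Alternatives covered the background correction, normalization, dim-probe filter, deposited values, replicate block, prior, array weights, outlier flags and each array left out. The normexp alternative used spot medians in place of the planned spot means, which were not used here, with an offset of 50 that compresses changes of dim spots; normexp without an offset and spot medians with no correction were added after the data had been seen. All arrays lay on 1 slide. Normoxia 1 to 3 and hypoxia 1 shared slide row 1 and the other hypoxia arrays lay in row 2, so the row was added as a block and row 1 was fitted alone; in both fits the oxygen effect rests on hypoxia 1, which is assumed to vary like the other arrays. No pair of arrays held an identical set of values. On simulated values for the hypoxia against normoxia comparison over 12024 probes, the fit recovered 38% of probes changed 2-fold, 92% at 4-fold, 98% at 8-fold and 100% at 16-fold, with 10 false calls among 174. With the replicate block it recovered 90% at 2-fold, with 10 false calls among 205. The simulated noise was independent between arrays and between probes, and the blocked values were simulated with the pairing as true. These shares therefore do not test the pairing, and the false calls do not cover probes that vary together. The shares also hold for 50 changed probes at each fold, and fewer changed probes would make the adjustment stricter.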

Results

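The circRNA content of rat lung was measured after 21 days in 10% oxygen, an exposure used to model pulmonary arterial hypertension, and compared with lung of rats kept in normoxia. Each group held 3 arrays. Between 11287 and 12266 of the 14145 circRNA probes were well above background on an array, and 10911 were so on all 6. The 75th percentile of the signal lay between 92.6 and 171.4. No non-control spot was saturated.

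Without the replicate number as a block, 8 of the 9 circRNAs that passed the adjusted threshold were lower in hypoxic lung; with it, 185 were higher and 196 lower. The circRNA ASCRPR007618 fell by 5.18 on the log2 scale (SE 0.36, limma adjusted p = 0.0046), from 2.16 ± 0.44 in normoxia to -3.02 ± 0.62 in hypoxia relative to the 75th percentile (SD, n = 3). ASCRPR004694 fell by 5.18 as well (SE 0.17, limma adjusted p = 1.25e-04), from 1.15 ± 0.18 to -4.03 ± 0.10 (SD, n = 3). It was well above background on 1 of the 3 hypoxia arrays, so the size of its change is uncertain: in spot medians with no background correction the changes of ASCRPR007618 and ASCRPR004694 were -3.88 and -3.22. ASCRPR010205 was the circRNA that rose, by 1.76 (SE 0.18, limma adjusted p = 0.037), from 0.02 ± 0.19 to 1.79 ± 0.18 (SD, n = 3). ASCRPR010377 had an estimate of 1.51 (SE 0.20) that did not pass (limma adjusted p = 0.10). It passed with the replicate block (limma adjusted p = 0.028), though not once pair 3 was left out of it (0.15), and without the block under an intensity trend with a robust prior (0.038), under array weights (0.0020) and in uncorrected spot medians (0.042). The array weights rested mainly on normoxia 3 and hypoxia 3. The call of ASCRPR010205 ended when any one of the 6 arrays was left out (limma adjusted p from 0.053 to 0.38), with quantile normalization (0.053) and without the filter on dim probes (0.062), and that of ASCRPR007618 ended without normoxia 3 (0.080). Normexp correction of spot medians with an offset of 50, which compresses the changes of dim spots, ended the calls of ASCRPR007618 (0.17), ASCRPR004694 (0.42) and ASCRPR010205 (0.17), with log2 changes of -2.88, -2.14 and 1.34. Without the offset the changes were -4.15, -3.63 and 1.57 and none of these passed (0.82 for each). For each of these circRNAs the 3 arrays of one group lay apart from the 3 of the other, which the rule for naming them required. The plot shows the single arrays. The files pair none of them with a host gene.

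**Figure D1:**
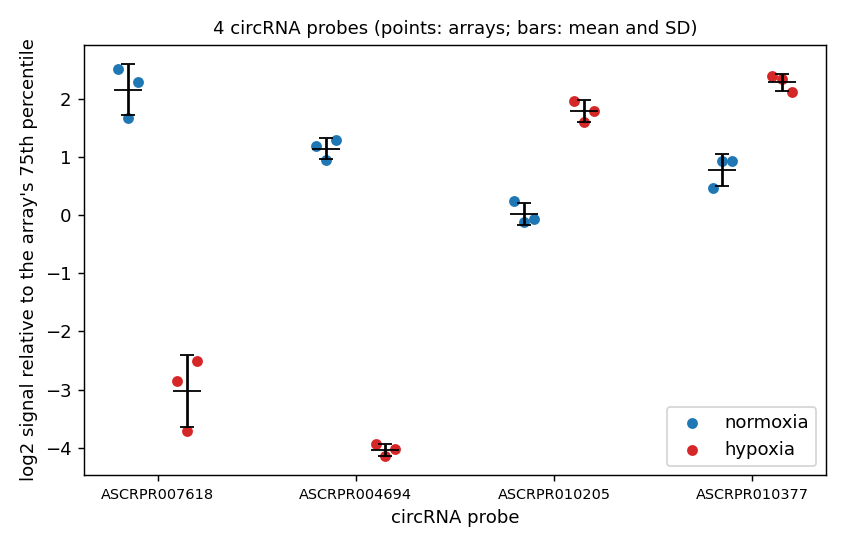
Signal of 4 circRNA probes on each array, in log2 units relative to the 75th percentile of the array, with normoxia in blue and hypoxia in red; bars give the mean and SD of 3 arrays. ASCRPR007618 and ASCRPR004694 are lower in hypoxia, and ASCRPR010205 and ASCRPR010377 lie higher, the last without passing the adjusted threshold.

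In all, 9 of 12024 circRNAs passed, 8 lower and 1 higher in hypoxia. The 8 lower circRNAs had log2 changes from -5.18 to -1.76, and 5 of those measured above background on at least 1 hypoxia array changed 4-fold or more. Of these 8, 6 were well above background on all 3 hypoxia arrays and 1 on none, so that its change is only a bound. The groups did not overlap for any of the 9. Across all circRNAs tested, 2470 (20.5%) had groups that did not overlap. Chance would give 10% for exchangeable arrays, which these were not: the other splits of the 6 arrays gave from 2.9% to 23.7%. The 3 of them that part all pairs, as the real one does, gave 2.9%, 4% and 6%, but the pairs were taken from these same values. The looser threshold was met by 1148 circRNAs, 412 higher and 736 lower. That direction turned under normexp without an offset (289 higher, 176 lower), which also shifted the median change to 0.22. It turned as well with the replicate block on quantile-normalized values (927 higher, 881 lower) and on deposited values (367 higher, 329 lower). At any fold 1707 had an unadjusted p under 0.05, against 601 for independent arrays with no change. This number was 3353 with the replicate block, 410 under normexp with an offset of 50 and 491 without the offset, 484 in slide row 1 alone, and from 855 without normoxia 3 to 3171 without normoxia 2 when 1 array was left out. With the replicate number as a block, 381 circRNAs passed, 185 higher and 196 lower, among them all 9 of the first count; their median change was 2.18-fold. The balance and the number depended on the scaling: the block gave 53 higher and 42 lower with quantile normalization and 108 higher and 51 lower with the deposited values. Without pair 3 the blocked fit called 0 higher and 7 lower, 6 of the 9 among them. With all 3 pairs in the block the looser count was 1846.

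**Figure D2:**
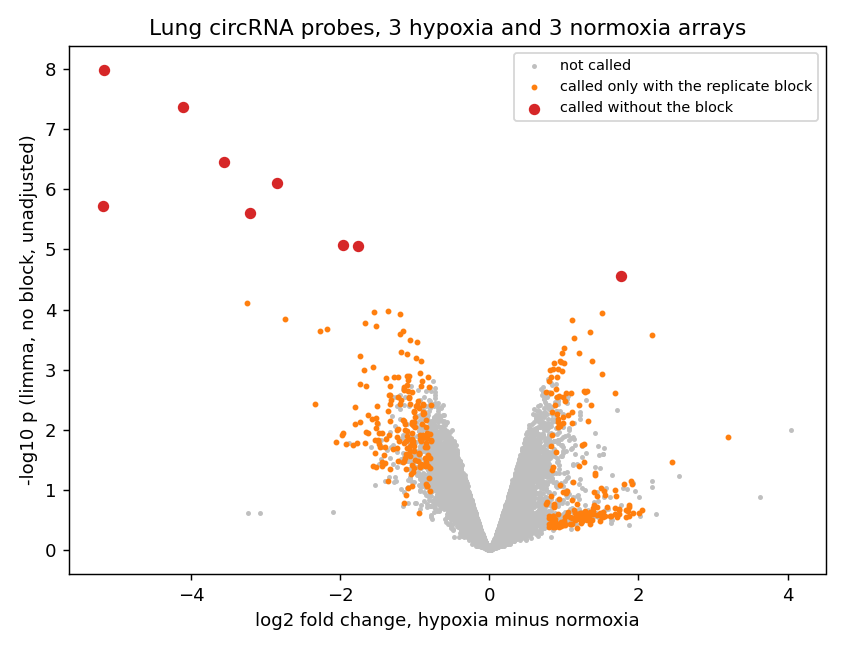
Change of each circRNA (log2, hypoxia minus normoxia) against the negative log10 of its unadjusted limma p without the block. The 9 red points passed the adjusted threshold without the replicate block, 8 of them on the lower side; orange points passed only with it.

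Quantile normalization gave 8 circRNAs, 0 higher and 8 lower, and the deposited log2 values gave 8, 2 higher and 6 lower. Row 2 of the slide held hypoxia arrays only, so with slide row as a block, as in row 1 alone, the oxygen effect rests on hypoxia 1. With the block 12 circRNAs passed (8 higher, 4 lower), of which 4 were among the 9, and in row 1 alone 9 passed (6 higher, 3 lower), of which 3 were. ASCRPR007618 then had a log2 change of -5.004, ASCRPR004694 of -5.08 and ASCRPR010205 of 1.95; with the row as a block ASCRPR004694 kept its call (limma adjusted p = 0.0044), and ASCRPR007618 (limma adjusted p = 0.059) and ASCRPR010205 (limma adjusted p = 0.16) lost theirs. The count of 9 became 1 under normexp correction with an offset of 50, 0 without the offset and 13 in uncorrected spot medians, 8 of the 9 among them. It was 33 without normoxia 2 and 4 without normoxia 3, while limma array weights, which rested mainly on normoxia 3 and hypoxia 3, gave 5016.

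Probes of linear transcripts measured what remained of them after RNase R, which depends on the digestion as well as on the level of the messenger RNA. Among 34 linear transcript probes, 2 passed, both lower in hypoxia and both without a gene symbol. They were singled out after their values were seen. The transcript ENSRNOT00000072358 fell by 1.20 on the log2 scale (SE 0.20, limma adjusted p = 0.0072), and the transcript M15402 fell by 1.65 (SE 0.38, limma adjusted p = 0.030). The M15402 probe was above background on 2 of the 3 hypoxia arrays. Under normexp correction with an offset of 50, 0 of the 34 passed, and these estimates shrank to -0.42 and -0.10, and without any one of the 3 normoxia arrays 1 passed. Without the adjustment 4 of the 34 had p under 0.05, and 7 with the replicate block.

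None of the 23 tested probes of 22 named genes passed the adjusted limma test at the main settings, and 1 of them, Pop7, had an unadjusted p under 0.05. With the replicate block none passed either, and 3 had an unadjusted p under 0.05: Pop7, lower in all 3 pairs, and Ndfip1 and Nat1, higher in all 3. The hypoxia response and glycolysis list was represented by Ldha, a lactate dehydrogenase subunit, Pgk1, the phosphoglycerate kinase, and Pdk3, a kinase that inhibits pyruvate dehydrogenase. In this hypoxia response and glycolysis list 0 of 4 probes passed, adjusted over all probes or adjusted over the list alone (limma adjusted p from 0.501 to 0.723). The estimates were 0.08 and 0.31 for the Ldha probes, 0.39 for Pdk3 (SE 0.32; 0.78 under array weights, where it passed with limma adjusted p = 0.0070) and 0.16 for Pgk1 (SE 0.25). The weights were 5.08 for normoxia 3, 6.24 for hypoxia 3 and under 1 elsewhere, so the weighted fit rested largely on 1 array per group. Nlrp3, an inflammasome sensor, had an estimate of 0.10 (SE 0.25) and was the single tested member of the inflammation list. Of the neuronal list, Dlg4, a postsynaptic scaffold, had 0.24 (SE 0.20; 0.37 under array weights, where it passed with limma adjusted p = 0.021) and Map2, a microtubule-associated protein, had -0.09 (SE 0.25; 0.093 with quantile normalization and under normexp 0.25 with an offset of 50 and 0.92 without); adjusted over the list alone, 0 passed in either list. Nlrp3 was above background on 1 normoxia and 2 hypoxia arrays, and Map2 on 2 normoxia arrays and 1 hypoxia array. Fgf2, of the growth factor list, was not well above background on any array.

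Reference genes varied by similar amounts. Actb had an estimate of 0.42 (SE 0.26, limma adjusted p = 0.46), B2m 0.11, Hsp90ab1 0.01, Rplp1 0.21, Rpl13a -0.22, Sdha -0.10 and Gusb -0.33. Cyp2e1, a cytochrome P450, had 0.55 (SE 0.32), Ndfip1 0.49 (SE 0.29) and Nat1 0.45 (SE 0.23), with limma adjusted p of 0.46, 0.46 and 0.43. Under array weights these 3 passed, with 0.65, 0.49 and 0.56 (limma adjusted p = 0.014, 0.021 and 0.012), as did Rpl13a with -0.67 (limma adjusted p = 0.014) and Gusb with -0.43 (limma adjusted p = 0.016). The weighted fit rested largely on normoxia 3 and hypoxia 3. Pop7 had -0.64 (SE 0.26, limma adjusted p = 0.33), and under normexp correction 0.17 with an offset of 50 and 0.58 without. The Pop7 probe was above background on 1 of the 3 hypoxia arrays. Eif4b, Med16, Pdcd10, Slc28a2 and Odf2l had estimates of -0.21, -0.27, -0.15, -0.08 and 0.25. The sign for Odf2l rested on 1 array: the signal was -2.34 on hypoxia 1 and -3.94 and -4.17 on the other hypoxia arrays, and the estimate was -0.33 without hypoxia 1. Another 16 probes of named genes, Hprt1, Cdh2, Gdnf and Ptk2b among them, were above background on too few arrays to be tested.

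**Figure D3:**
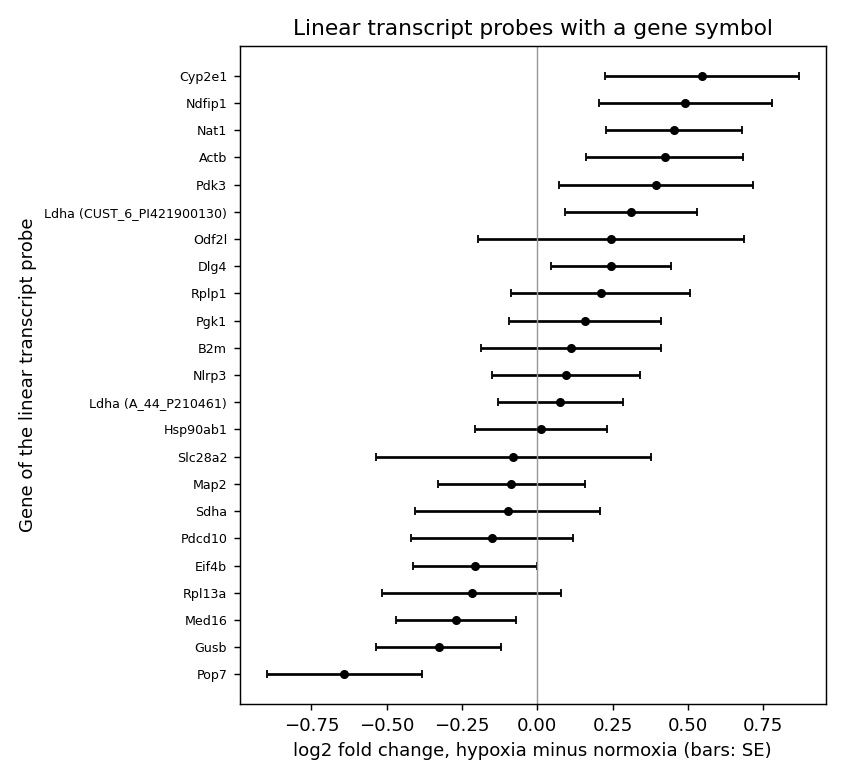
Change of each linear transcript probe with a gene symbol, in log2 units, hypoxia minus normoxia, over 3 arrays per group; bars give the SE. The 23 estimates run from -0.64 for Pop7 to 0.55 for Cyp2e1, and none passed the adjusted threshold in the fit shown; several change sign under other scalings, Pop7 to 0.17 under normexp correction with an offset of 50.

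Array quality was compared in 6 measures. The share of non-control spots well above background was 81.2% ± 3.79 in normoxia and 80.5% ± 0.97 in hypoxia (SD, n = 3, exact permutation p = 0.90). The median background was 20 on every normoxia array and 18.3 ± 0.58 in hypoxia (SD, n = 3, exact permutation p = 0.10, the smallest this design allows, 0.60 after adjustment). The median signal of the linear probes was -1.55 ± 0.27 and -1.59 ± 0.20 (SD, n = 3, exact permutation p = 0.90). The log2 75th percentile was 6.88 ± 0.48 in normoxia and 7.23 ± 0.22 in hypoxia (SD, n = 3, exact permutation p = 0.40). The log2 signal of the control probe eQC-41 was 8.07 ± 2.58 and 9.83 ± 1.08 (SD, n = 3, exact permutation p = 0.40). Correlations between arrays were 0.908 to 0.969 within groups and 0.860 to 0.977 between them. The first principal component held 59.3% of the variance and followed the log2 signal of the positive control probe eQC-41, singled out after the values had been seen, over the 6 arrays (Pearson's r = 0.973, exact permutation p = 0.0014, 0.0056 after adjustment over 4 relations and 0.0042 over the 13 control probes above background on every array; Spearman's rho = 1, exact permutation p = 0.0028). Without normoxia 1 and hypoxia 2 r was 0.958. Over the 13 control probes r ran from -0.55 to 0.97, with a median of 0.53 (exact permutation p = 0.23). Row 2 of the slide held 2 arrays of 1 group. Row 1 held 4 arrays, whose order was the same in the first principal component and in the eQC-41 signal. No correlation was computed within rows.

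**Figure D4:**
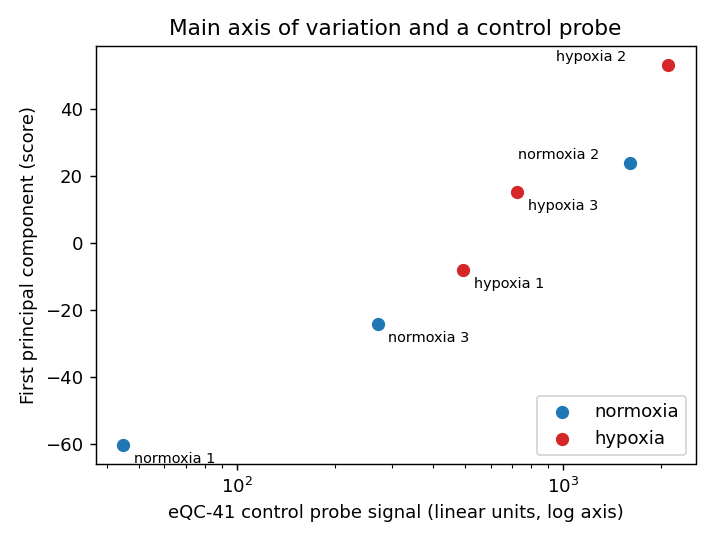
First principal component of the circRNA values (score) against the signal of the control probe eQC-41 (linear units on a log axis), 1 point per array. The order of the 6 arrays is the same on both axes, with normoxia 1 lowest and hypoxia 2 highest.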

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

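The slide row, control probe covariate, offset-free normexp, uncorrected spot medians, undetrended signal, flag exclusion, blocked combinations and all linear transcript tests were chosen after the data had been seen. The planned slide block was not run, since all arrays shared 1 slide, and the host gene list and class tests had no host genes to use. The count of 9 circRNAs became 1 under normexp with an offset of 50 (which also shifted the median change to 0.10), 0 under normexp without an offset (a shift to 0.22), 381 with the replicate block, 5016 with array weights (which gave normoxia 3 and hypoxia 3 weights of 5.08 and 6.24 and every other array under 1), 95 with the replicate block and quantile normalization (53 higher, 42 lower) and 159 with the replicate block and deposited values (108 higher, 51 lower). It ran from 4 to 33 when 1 array was left out, and the blocked count from 7 to 519 when 1 pair was (7 without pair 3, 406 without pair 1). The looser count of 1148 became 205 under normexp with the offset and 465 without (289 higher, 176 lower, the other direction), 440 in uncorrected spot medians, 379 with deposited values, 1846 with the replicate block, 2562 with array weights, 734 with the row as a block, 484 in row 1 alone, 1808 and 696 with the replicate block on quantile-normalized and deposited values, 658 to 2448 with 1 array left out and 1617 to 2722 with 1 pair left out of the block. The 2 linear probes became 0 under normexp with and without the offset, 1 with probes above background on all 6 arrays, 13 with array weights, 4 with the row as a block, 1 with the replicate block and quantile normalization, 1 to 2 with 1 array left out and 0 to 3 with 1 pair left out. The other counts stayed within 1.5 times, among them 13 in uncorrected spot medians (4 higher, 9 lower). The calls lost under normexp did not return without the offset, and why these counts moved was not tested. In both row fits the oxygen effect rests on hypoxia 1, the calls of Odf2l included. Signs of the 4 named circRNAs held throughout: ASCRPR007618 ran from -5.43 to -2.88 and passed in 24 of 28 alternatives (adjusted p 1.87e-05 to 0.82), ASCRPR004694 from -5.30 to -2.14 in 25 of 27 (7.12e-07 to 0.82), ASCRPR010205 from 1.34 to 1.95 in 15 of 28 (2.37e-04 to 0.82) and ASCRPR010377 from 1.26 to 1.67 in 8 of 28 (0.0020 to 0.94). With the replicate block ASCRPR010377 gained its call, and no other named result changed. Of 593 values of the 23 named linear probes, 9 passed: Pdk3, Cyp2e1, Nat1, Ndfip1 and Dlg4 higher and Rpl13a and Gusb lower with array weights, and Odf2l higher with the row as a block and in row 1 alone. Another 67, from 16 probes and none of them past the threshold, had the other sign. Under normexp with the offset these were Pop7 0.17, Pdcd10 0.044, Slc28a2 0.15, Map2 0.25, Sdha 0.13 and Gusb 0.18; without it Pop7 0.58, Pdcd10 0.14, Slc28a2 0.42, Map2 0.92, an Ldha probe -0.058, Sdha 0.38, B2m -0.023, Hsp90ab1 -0.083 and Gusb 0.60; in uncorrected spot medians Nat1 -0.070, Nlrp3 -0.20, Odf2l -0.10, Pdk3 -0.11, Rplp1 -0.0026 and Pgk1 -0.13; under quantile normalization, with or without the replicate block, Map2 0.093 and Hsp90ab1 -0.084; with the percentile over detected probes Hsp90ab1 -0.0095; with array weights Nlrp3 -0.12, Odf2l -0.042, Rplp1 -0.013, B2m -0.31, Pgk1 -0.25 and Hsp90ab1 -0.12. With 1 array left out the ranges that crossed 0 were Slc28a2 -0.56 to 0.24, Map2 -0.21 to 0.10, Ldha (the probe with 0.08) -0.029 to 0.17, Nlrp3 -0.13 to 0.21, Odf2l -0.33 to 0.59, Rplp1 -0.10 to 0.38, Sdha -0.32 to 0.14, B2m -0.12 to 0.44, Pgk1 -0.0089 to 0.33, Rpl13a -0.41 to 0.091 and Hsp90ab1 -0.11 to 0.15. With the row as a block and in row 1 alone they were Rplp1 -0.055 and Hsp90ab1 -0.034; with the control probe as covariate Pdcd10 0.12, Nlrp3 -0.12, Rplp1 -0.10, Pgk1 -0.028 and Hsp90ab1 -0.040. In the block without pair 1 they were Nlrp3 -0.11, Odf2l -0.19, B2m -0.11, Pgk1 -0.041 and Hsp90ab1 -0.089, and without pair 3 Slc28a2 0.13, Map2 0.016, the same Ldha probe -0.015 and Rpl13a 0.059. Signal over background limits the dim probes: ASCRPR004694 was above it on 1 of 3 hypoxia arrays.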

Other observations

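The tests of the slide row, of background subtraction, of the control probes and of other splits for the unblocked circRNA counts were chosen after the results they bear on had been seen.

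Some circRNAs were far lower in hypoxia with little spread in either group. Background subtraction of dim spots enlarged these changes and is left open as a partial source. Only circRNAs called without the replicate block were checked. Of the 6 called lower by 2 log2 units or more, 5 were still lower by that much in spot medians with no background subtracted. The median change of the 6 was -3.01 in place of -3.84. The circRNA that was above background on no hypoxia array had -0.81. Differences between single rats or single arrays, unrelated to oxygen, may account for part of it. At least 2 log2 units parted the oxygen groups for 7 circRNAs, and no other split of 3 against 3 arrays had over 5. For 41 circRNAs normoxia 1 lay apart from the other arrays, a split that needs only 1 deviant array. Normoxia 1 alone lacked the multiplicative detrending and had the lowest eQC-41 signal, so rat and array cannot be told apart there. The row of the slide stays open, since only 1 hypoxia array shared the row of the normoxia arrays, and 1 array excludes nothing. For 9 of the 9 circRNAs this array lay nearer to the other hypoxia arrays. The 9 were called with it in the hypoxia group, so this nearness was largely set by the selection and decides nothing. The oxygen exposure itself is the biological explanation that the design names and also stays open.

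Arrays of the same replicate number deviated together. Overall brightness of the kind that quantile normalization removes is argued against as the only source, since the lowest correlation within a pair was 0.21 after it. Brightness that acts unevenly on probes stays open. The first principal component had r = 0.77 with the log2 75th percentile of the arrays (exact permutation p = 0.078, 0.16 after adjustment over 4 relations). A step of labelling or hybridisation that control spots also record may contribute but is undecided. The control probe eQC-41, picked after the data had been seen, followed the first principal component with r = 0.973. GE_BrightCorner, the brightest control probe, had r = 0.91, and the rest had signals of at most 71.7. Of all 13 control probes above background 7 had r over 0.5, and the median was 0.53 (exact permutation p = 0.23). For linear RNA left after RNase R, r was 0.70 (exact permutation p = 0.13) and 0.10 without normoxia 1 and hypoxia 2, which leaves it undecided. Whether paired handling of the animals contributed, or whether the numbers matched by chance, was not tested.

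The 6 arrays allow 10 splits of 3 against 3, too few for a share under 0.05. For the count at the adjusted threshold the real split gave 9 and the highest other 0 (1 of 10 splits gave as many). The looser count was 1148, and 2 of 10 splits gave as many; the split of normoxia 1, normoxia 3 and hypoxia 1 from the rest gave 1718, which points to a structure of the samples along the first principal component. That split parts 1 pair. Among the splits that part all 3 pairs, as the real one does, the highest other looser count was 111. The pairs were taken from these same values, so this restriction gives no independent support, and the same holds for the blocked count. With the replicate block, the real split gave 381 and the highest of the other splits parting all 3 pairs 0 (1 of 4 gave as many, also too few). For linear transcripts the real split gave 2 and the highest other 0 (1 of 10).

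Spots of a linear probe within an array had a median SD of 0.11 log2 units, against 0.32 between arrays of a group. The signal of eQC-41 was 44.8, 1599 and 270 on normoxia 1 to 3 and 495, 2102 and 724 on hypoxia 1 to 3.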
